A study of Mus musculus with 23 samples.

How the data were processed

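The series holds RNA-seq of mouse quadriceps muscle from 23 animals of the C57BL/6 background. Per the labels' protocols, mice were kept on a standard chow diet and were occasionally given glucose and exercise tolerance tests. Total RNA was purified with miRNeasy (7 months) or Trizol (4 and 24 months), and poly(A) RNA was selected with oligo dT beads, fragmented and made into libraries with an Illumina mRNA-seq kit, per the labels' protocols. The strand of the libraries is not stated, so reads from genes that overlap on opposite strands cannot be told apart. Sex is not given for any animal. The groups, taken from the labelled genotype and age, were WT at 4, 7 and 24 months (WT_4m, WT_7m, WT_24m, 4 libraries each), mNKO at 7 months (mNKO_7m, 4 libraries), and MCK-NamptOE at 4 months (OE_4m, 3 libraries) and 24 months (OE_24m, 4 libraries). Each title names another animal, so each library was treated as an independent replicate. Replicates are numbered within a group for reference only.

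The authors deposited 23 files of raw counts per gene and 5 tables of test results. Per the submitters' processing notes, cutadapt 1.4.2, TopHat2, HTSeq, DESeq2 and DESeq were used with genome build mm10, and neither their order nor their settings are given. Each count file lists 38924 genes and 5 summary lines for reads not assigned to a gene, which stayed out of every library size and test. Those lines made up 21.53 to 33.5% of the file totals at 7 months and 33.58 to 40.02% at 4 and 24 months. The deposited tables hold a mean of normalised counts, a log2 fold change with its standard error, and a raw and an adjusted p-value per gene, per the file headers. The 4 deposited tables of the 4- and 24-month groups share the same mean, to rounding, for the genes listed in common, so their counts were normalised together. Gene symbols came from the deposited tables (19905 genes) or, for 17990 others, from a reference annotation (release M21), and 1029 genes had no symbol. Positions were found for 37607 genes.

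Libraries at 7 months held 14900674 to 22755930 counts on genes, and those at 4 and 24 months 2032544 to 3443762. Genes with low counts were removed with edgeR's filterByExpr, which left 13140 genes (99.93% of the counts) at 7 months and 9144 genes (99.53%) at 4 and 24 months. Libraries were scaled by TMM, with factors of 0.752 to 1.286 and 0.921 to 1.085. The common dispersion was 0.0504 (biological coefficient of variation 22.4%) at 7 months and 0.0256 (16%) at 4 and 24 months, and the median standard error of a log2 fold change was 0.186 and 0.206.

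The 8 libraries at 7 months and the 15 libraries at 4 and 24 months were fitted apart, since their RNA was extracted differently, with a mean per group and 6 and 11 residual degrees of freedom. Genes were tested with edgeR 4.0.16 (robust quasi-likelihood F test) in R 4.3.3, and a gene was called changed at a Benjamini-Hochberg adjusted p below 0.05. The 6 comparisons were mNKO with WT at 7 months, MCK-NamptOE with WT at 4 and at 24 months, 24 with 4 months in WT and in MCK-NamptOE, and the difference between the last 2 (interaction). These p-values measure the spread between these mice. The groups, comparisons, tests, gene lists and the rule for named genes were fixed before the data were examined. The named genes are Nampt, the 10 largest rises and the 10 largest falls of each comparison with an adjusted p below 0.05, a mean of at least 1 CPM and no overlap between the groups, and up to 4 members per gene list, those with the smallest p among the changed or, where none changed, the most expressed. Predicted genes, pseudogenes and sex-linked genes were counted but named only where a list holds them. A few genes that the rule names are not reported here.

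The 40 gene lists cover NAD metabolism, mitochondria, energy metabolism, fibre types, muscle regeneration and atrophy, stress responses, the clock, and markers of other cell types. Lists with at least 3 tested members were tested with camera in limma 3.58.1 with a preset correlation of 0.01 between genes, against all other genes, and p-values were adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. Members were also counted with p-values adjusted over the list alone. Changes in different comparisons were set against each other by Pearson and Spearman correlation across genes tested in both, by counts of shared calls beside those expected of independent lists, and by reading genes called in a comparison in the others. Per-library values are normalised CPM, and list means use log2 CPM with a prior count of 2. For genes with few WT reads, ratios of summed counts are given with exact 95% counting intervals, and a gene with no WT reads is given as a lower bound against a floor of 3 counts per library.

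The test was checked on simulated data with changes put into 200 genes per comparison, and its recovery is given with the alternatives below. Alternatives fixed beforehand were DESeq2 size factors, no filter on low counts, a filter at 1 CPM, the DESeq2 1.42.0 Wald test, limma-voom with sample quality weights, a fit of all 23 libraries, a fit of only the groups compared, and leaving out each library in turn. Alternatives added after seeing the data were total counts with no further scaling, TMM without mitochondrial genes and the 20 most abundant genes, leaving out OE_4m replicate 3 and OE_24m replicate 4 together, and the mean of slow fibre genes in each library as a covariate. Every split of the libraries of a comparison into groups of the same sizes, or 100 drawn splits for the interaction, was refitted. Length, GC content and expression were matched in 10000 draws from the 50 nearest genes of each list member. Files were read and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The reads were not realigned, since raw sequence was not available here.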

Results

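Messenger RNA of quadriceps muscle was sequenced in 23 libraries, each from a separate mouse of the C57BL/6 background. Wild-type (WT) mice were sampled at 4, 7 and 24 months of age, with 4 libraries at each age. Mice deficient for Nampt in skeletal muscle, named mNKO, were sampled at 7 months (4 libraries). Mice overexpressing Nampt in skeletal muscle, named MCK-NamptOE, were sampled at 4 months (3 libraries) and at 24 months (4 libraries). Nampt encodes the rate-limiting enzyme of the salvage pathway that makes the coenzyme NAD from nicotinamide. The 8 libraries at 7 months held 14900674 to 22755930 counts on genes, and the 15 libraries at 4 and 24 months held 2032544 to 3443762, so weakly expressed genes were measured less precisely in the second set. Levels are given as CPM (counts scaled to library size), as mean ± SD over the libraries of a group, with the group sizes above. Fold changes and adjusted p-values for genes come from edgeR's quasi-likelihood test, and those for gene lists come from camera.

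Nampt itself lies on chromosome 12, positions 32819545 to 32853349 on the plus strand of the mouse genome (gene ENSMUSG00000020572.7). Its transcript fell to 15.6% of the WT level in mNKO muscle, from 119.5 ± 11.8 CPM to 18.6 ± 4.51 CPM (log2 fold change -2.68, SE 0.18, adjusted p = 3.62e-06), and every mNKO library lay below every WT library. In MCK-NamptOE muscle it rose 23.2-fold at 4 months, from 219.4 ± 23.1 to 5080 ± 632 CPM (log2 fold change 4.53, SE 0.21, adjusted p = 1.84e-12). At 24 months it rose 30.2-fold, from 205.2 ± 12.1 to 6200 ± 2332 CPM (log2 fold change 4.92, SE 0.21, adjusted p = 2.84e-13). OE_24m replicate 4 held 9533 CPM and the other OE_24m libraries 4107 to 5736 CPM. The difference between the rises at 24 and 4 months did not pass edgeR's test (0.38, SE 0.26, adjusted p = 0.91). With age Nampt did not pass the test in WT (log2 fold change -0.09, SE 0.18, adjusted p = 0.949) or in MCK-NamptOE muscle (0.29, SE 0.19, adjusted p = 0.632).

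**Figure D1:**
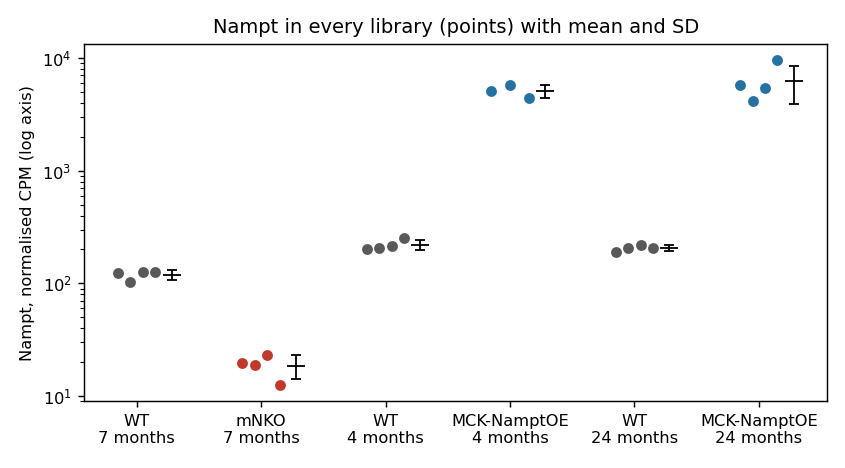
Nampt transcript in every library (points), in normalised CPM on a log axis, with the mean and SD of each group beside them. The mNKO group averaged 18.6 CPM against 119.5 CPM in WT at 7 months, and the MCK-NamptOE groups averaged 5080 and 6200 CPM against 219.4 and 205.2 CPM in WT at 4 and 24 months.

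The comparison of mNKO with WT at 7 months asks what the loss of Nampt does to the muscle's transcripts. In mNKO muscle, the lists of extracellular matrix, macrophage, antigen presentation, interferon response, myogenic regeneration, slow fibre and cell cycle genes stood higher by camera. The lists of fast fibre, calcium handling, glycogen and mitochondrial genes stood lower, although the medians of the calcium, glycogen and nuclear mitochondrial lists turn positive with total-count scaling. Of the 20 lists that passed camera, 0 passed with an estimated correlation (adjusted p from 0.125 to 0.728), while fry passed 27 lists, 19 of them among the 20. Perinatal myosin heavy chain Myh8, normally a marker of developing or regenerating fibres, rose 99.9-fold, from 2.52 ± 1.42 to 252 ± 122 CPM. Tmem8c (myomaker, needed for myoblast fusion) rose 121-fold, from 0.373 ± 0.593 to 44.7 ± 6.97 CPM (539-fold without WT_7m replicate 4), and the slow troponin Tnni1 rose 106-fold, from 0.983 ± 0.622 to 104 ± 15.6 CPM. In the other direction, Mstn (myostatin, which restrains muscle growth) fell from 52.6 ± 9.87 to 5.28 ± 2.6 CPM.

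Of 13140 genes tested, 6974 changed, 3759 higher and 3215 lower, and 2522 of the rises and 986 of the falls were at least 2-fold. The libraries of both groups did not overlap for 50.11% of the genes, against 2.86% expected by chance. The largest rises that the naming rule picked, besides Myh8, Tmem8c and Tnni1, were the macrophage elastase Mmp12 (log2 fold change 7.55, SE 1.33), the cell cycle inhibitor Cdkn2a (6.53, SE 0.52), the B cell and macrophage receptor Cd72 (6.80, SE 0.75), Msln, F10, Sprr1a and the immunoglobulin Ighg3. Mmp12 and Tmem8c were highest among WT libraries in WT_7m replicate 4, at 4.74 and 1.26 CPM. Without that library the log2 fold changes of Mmp12, Tmem8c and Cdkn2a were 11.15, 9.07 and 7.77, and that of Cd72 was 7.55 without WT_7m replicate 2 and 6.19 without mNKO_7m replicate 4. Msln, F10 and Sprr1a had 1, 2 and 1 reads over the 4 WT libraries, and the ratios of their totals were 268 (95% counting interval 47.8 to 10600), 126 (34.6 to 1040) and 141 (25 to 5610). Ighg3 had no read in WT and 3 ± 3.58 CPM in mNKO, at least 17.2-fold above a floor of 3 reads per WT library, or 7.02-fold without mNKO_7m replicate 3. F10, Msln and Sprr1a had no WT read without WT_7m replicates 4, 1 and 2, in that order, and were then at least 21.5-, 21.6- and 12.1-fold above the floor. These intervals and the floor cover counting error only. The largest falls were Cdh4 (log2 fold change -6.60, SE 0.53), Efcab6 (-5.68, SE 0.70), Dusp26 (-4.56, SE 0.37), Htra4 (-4.55, SE 0.56), Dkk3 (-4.51, SE 0.82), the potassium channel subunit Kcnab1 (-4.46, SE 0.28), the muscle-secreted peptide Ostn (-4.33, SE 0.80), BC049352 (-4.21, SE 0.69), Ppp1r1a (-4.02, SE 0.47) and Tmem132b (-3.95, SE 0.43). Without mNKO_7m replicate 2, Cdh4, Efcab6 and Ostn stood at -7.20, -6.31 and -5.05, and without WT_7m replicate 2, Dkk3 and BC049352 stood at -3.81 and -3.43. Adjusted p-values of these 20 genes ran no higher than 0.0113, that of Ighg3.

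All 37 measured genes of the extracellular matrix list rose (median log2 fold change 2.5, adjusted p = 2.33e-33, but adjusted p = 0.16 with an estimated correlation). Examples are the matrix glycoproteins Comp (5.18, SE 0.28), Cilp (4.04, SE 0.21) and Thbs4 (4.02, SE 0.22), and the collagen Col8a1 (3.93, SE 0.22). Tendon markers followed, with 7 of 9 rising (8 adjusted over the list alone), among them the joint lubricant Prg4 (4.05, SE 0.48) and dermatopontin, Dpt (1.5, SE 0.23), at adjusted p = 0.000325 and adjusted p = 0.328 with an estimated correlation. Thbs4 and Fmod belong to both lists. All 30 macrophage and monocyte markers rose (median 3.76, adjusted p = 7.63e-13, adjusted p = 0.427 with an estimated correlation), for example the cysteine protease Ctsk (4.03, SE 0.40), Itgam (3.28, SE 0.37), the lipopolysaccharide co-receptor Cd14 (3.26, SE 0.32) and the chemokine receptor Ccr2 (2.85, SE 0.28). All 18 antigen presentation genes rose (median 1.93, adjusted p = 1.85e-10, adjusted p = 0.427 with an estimated correlation), including H2-Aa (3.25, SE 0.34) and B2m (1.51, SE 0.17). Class I and class II histocompatibility genes resemble each other, so the split of reads among them is uncertain.

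The interferon response had 25 of 28 genes rising (27 adjusted over the list alone), such as Zbp1 (3.57, SE 0.49) and Oas1a (3.47, SE 0.40), at adjusted p = 1.33e-06 and adjusted p = 0.427 with an estimated correlation. Among chemokines and cytokines 15 of 21 rose and 1 fell (16 and 1 adjusted over the list alone), at adjusted p = 1.06e-05 and adjusted p = 0.199 with an estimated correlation. Ccl5 (4.67, SE 0.58) and the monocyte attractant Ccl2 (4.43, SE 0.38) were among them. Cell cycle genes rose in 16 of 19 cases, for example the mitotic kinase Aurkb (4.80, SE 0.55) and Ccnd1 (1.88, SE 0.15), at adjusted p = 7.49e-05 and adjusted p = 0.469 with an estimated correlation. Immediate early genes rose in 11 of 22 cases, Myc (2.15, SE 0.32) and Jund (1.41, SE 0.19) included. Their list passed at adjusted p = 0.019, with adjusted p = 0.704 with an estimated correlation and 0.079 without WT_7m replicate 4. In the integrated stress response list 12 of 24 genes rose and 3 fell. Asparagine synthetase, Asns (2.27, SE 0.28), and the amino acid transporter Slc7a5 (2.70, SE 0.27) rose. That list passed at adjusted p = 0.0437 (0.476 with an estimated correlation), kept its call in 5 of the 8 fits that left out a library, and reached 0.0621 without mNKO_7m replicate 4.

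The muscle genes moved apart by fibre type and developmental state. Myogenic regeneration had 18 of 25 genes rising and none falling (median 2.48, adjusted p = 8.39e-10, adjusted p = 0.195 with an estimated correlation), among them the embryonic light chain Myl4 (5.79, SE 0.27), the stress-responsive Ankrd1 (5.01, SE 0.35) and the growth factor Igf2 (3.5, SE 0.22). Slow fibre genes rose in 11 of 14 cases (median 3.04, adjusted p = 7.63e-13, adjusted p = 0.125 with an estimated correlation), with Tnnc1 (5.02, SE 0.24), Tnnt1 (4.66, SE 0.23) and the slow calcium pump Atp2a2 (1.90, SE 0.12). Fast fibre genes fell in 13 of 18 cases (14 adjusted over the list alone; median -0.94, adjusted p = 0.000156, adjusted p = 0.427 with an estimated correlation), including Ampd1 (-1.82, SE 0.24), Actn3 (-1.62, SE 0.21) and Mybpc2 (-1.32, SE 0.19). Myh1, the fast IIx myosin heavy chain, was the exception and rose (2.06, SE 0.28). The sarcomeric myosin heavy chains are similar in sequence, so counts of Myh1 and Myh8 are less certain than others. Denervation and neuromuscular junction genes rose in 11 of 19 cases and fell in 2 (adjusted p = 0.00747, adjusted p = 0.427 with an estimated correlation), with the fetal acetylcholine receptor subunit Chrng (6.18, SE 0.44; 7.24 without WT_7m replicate 4) and Chrna1 (2.88, SE 0.30).

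Among the lists that stood lower, transcripts of the mitochondrial genome fell in 9 of 10 cases (median -1.42, adjusted p = 0.000395, adjusted p = 0.427 with an estimated correlation), for example mt-Nd1 (-1.47, SE 0.23) and mt-Cytb (-1.10, SE 0.21). Mitochondrial genes took 10.3 ± 2.53% of the counts in mNKO and 17.2 ± 2.57% in WT (exact permutation p = 0.0286, adjusted p = 0.214 over 30 comparisons of library qualities). The mNKO libraries ran from 7.74 to 13.64% and the WT libraries from 13.85 to 19.65%. With 4 libraries a group no smaller exact p is possible, so the adjusted p cannot decide. With TMM scaling, nuclear complex I genes fell in 13 of 36 cases (10 adjusted over the list alone), tricarboxylic acid cycle genes in 13 of 20, regulators of mitochondrial biogenesis in 8 of 19 (7 adjusted over the list alone), and none of these genes rose in that scaling. Their medians were -0.38, -0.46 and -0.38, and with total-count scaling they turned to 0.15, 0.07 and 0.14, where 6, 4 and 4 genes rose and 0, 1 and 2 fell. Without WT_7m replicate 2 the complex I median was -0.24. Camera, which sets a list against all other genes, gave adjusted p = 0.00747, 0.00338 and 0.016 for these lists, and adjusted p = 0.728, 0.497 and 0.427 with an estimated correlation. Examples are Ndufb4 (-0.86, SE 0.18), Suclg2 (-1.16, SE 0.18), Idh3b (-0.78, SE 0.14) and the fusion protein Mfn1 (-0.90, SE 0.12).

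Glycolysis and glycogen genes fell in 15 of 29 cases and rose in 3, calcium handling genes fell in 13 of 26 and rose in 4 (6 adjusted over the list alone), and circadian clock genes fell in 9 of 18 and rose in 1. The medians of these lists were -0.44, -0.41 and -0.43 with TMM scaling and turned to 0.09, 0.11 and 0.09 with total-count scaling, where 7, 9 and 3 genes rose and 8, 9 and 5 fell. Without mNKO_7m replicate 2 the clock median was -0.71. Their adjusted p-values were 0.00747, 0.0072 and 0.00747, and adjusted p = 0.483, 0.483 and 0.427 with an estimated correlation. The glycogen phosphorylase kinase subunit Phkg1 (-1.16, SE 0.16), Gpd2 (-1.46, SE 0.21), the calcium release channel Ryr1 (-1.35, SE 0.17), the chloride channel Clcn1 (-1.40, SE 0.19), and the clock genes Arntl (-1.94, SE 0.21) and Nr1d1 (-1.45, SE 0.20) fell. Hexokinase 1, Hk1, went the other way (2.23, SE 0.18).

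**Figure D2:**
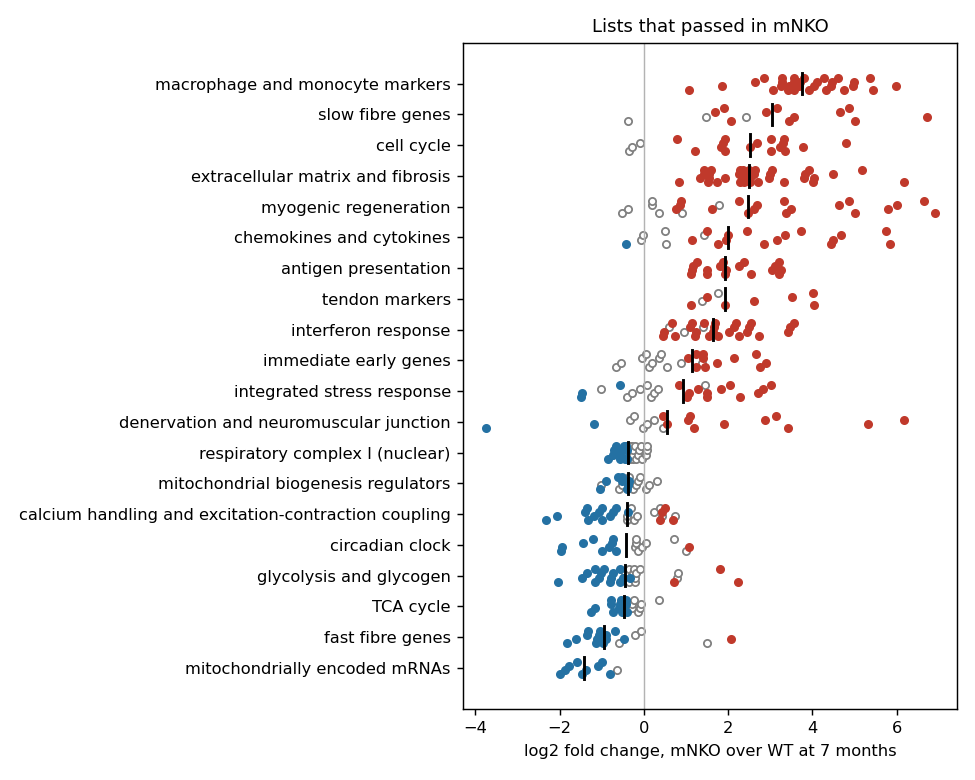
Log2 fold change (mNKO over WT at 7 months, horizontal axis) of every measured member of the 20 gene lists that passed camera. Filled points are genes that passed edgeR's test (red higher, blue lower), open points did not, and the black bar is the list median, from -1.42 for mitochondrially encoded mRNAs to 3.76 for macrophage and monocyte markers, and with total-count scaling the medians of complex I, biogenesis, calcium handling, circadian, glycolysis and TCA genes turn positive.

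The other 20 lists did not pass in mNKO (adjusted p from 0.0566 to 0.909), although single genes in them did with TMM scaling. T cell markers had 4 of 5 genes rising and 1 falling, with Il7r at 5.07 (SE 0.76), or 6.51 without WT_7m replicate 4. B and plasma cell markers had 5 of 10 rising and 1 falling. Igha (4.11, SE 0.39) and the joining chain Igj (3.10, SE 0.33) rose while Ighm (-2.04, SE 0.20) fell, and reads of immunoglobulin segments are shared in part. Neutrophil markers had 1 of 5 rising (Csf3r, 2.51, SE 0.36), endothelial markers 2 of 14 (Aplnr, 1.37, SE 0.30; 1 adjusted over the list alone), and Schwann cell markers 2 of 12 (Pmp22, 1.10, SE 0.13). Smooth muscle markers had 3 of 12 rising, Acta2 (1.01, SE 0.17) among them, and Myh11 (-0.82, SE 0.30) falling (3 and 0 adjusted over the list alone), a fall that did not pass without any of replicates 1, 2 and 4 of WT_7m or mNKO_7m (adjusted p from 0.0782 to 0.115), and none of 17 adipocyte markers passed. Among 5 red blood cell markers only the haem enzyme Fech fell (-1.0, SE 0.18), and 3 of 4 sex-linked genes fell, such as Ddx3y (-0.72, SE 0.20). The sex-linked falls depended on the scaling. Their list median was -0.53 with TMM and 0 with total counts, where 0 genes rose and 0 fell.

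Among 14 NAD synthesis genes 5 rose and 4 fell, Nampt and the mitochondrial NAD kinase Nadk2 (-1.42, SE 0.17) falling and Kmo (1.62, SE 0.30) rising. The 18 NAD-consuming enzymes also had 5 rising and 4 falling, with Bst1 (3.71, SE 0.67; 4.58 without WT_7m replicate 4), Sirt7 (1.29, SE 0.19) and Parp9 (1.13, SE 0.13) higher. Atrophy and autophagy genes rose in 8 and fell in 10 of 28 cases, with cathepsin L, Ctsl (1.16, SE 0.16), higher and Mstn (-3.32, SE 0.38) lower. Protein folding genes rose in 11 and fell in 4 of 22 (12 and 6 adjusted over the list alone), Hspb7 (2.44, SE 0.31) and Pdia4 (2.11, SE 0.17) among the rises. The list of p53, DNA damage and senescence genes had 7 of 23 rising, led by Cdkn2a, and 3 falling, with Ccng1 at -1.68 (SE 0.21). Antioxidant genes rose in 9 and fell in 7 of 28, with Hmox1 (2.05, SE 0.27) and Keap1 (-0.61, SE 0.10). Dystrophin complex genes rose in 6 and fell in 5 of 22, with Anxa2 (2.85, SE 0.20) among the rises. Lipid synthesis genes rose in 3 and fell in 4 of 20, with Me1 (-1.97, SE 0.21) and Srebf1 (-1.45, SE 0.18) lower. Fatty acid oxidation genes rose in 2 and fell in 8 of 26, with Cpt1a (1.6, SE 0.21) among the rises. Proteasome subunits rose in 1 (Psmb5, 0.60, SE 0.17) and fell in 7 of 31 (1 and 3 adjusted over the list alone). Respiratory complexes II to V rose in 2 and fell in 10 of 42 (2 and 7 adjusted over the list alone), with Cox6a1 at 1.35 (SE 0.22) and Cycs at -0.69 (SE 0.17). All these counts are with TMM scaling, and with total counts the balance shifts. There 7 NAD synthesis, 10 NAD-consuming, 14 atrophy, 14 folding, 17 p53, 13 antioxidant, 11 dystrophin complex, 5 lipid synthesis, 9 fatty acid oxidation, 14 proteasome and 14 complex II to V genes rose, and 2, 0, 5, 0, 1, 0, 2, 3, 0, 0 and 0 fell.

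Where no list-alone count is given, both adjustments gave the same count. Over all 800 listed genes, 296 rose and 172 fell, against 302 and 163 adjusted over the list alone. The split of the calls depended on the scaling. Total counts with no further scaling gave 6779 higher and 927 lower and an all-gene median log2 fold change of 0.538, against 0.014 with TMM, so every direction above is relative to the bulk of the tested genes. The authors' deposited table for this comparison held 7688 genes below an adjusted p of 0.05, 4184 higher and 3504 lower, and 6848 genes were called there and here in the same direction.

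Nampt overexpression at 4 months, compared with WT of that age, tests what added Nampt does in young muscle. Nampt was the only gene of 9144 tested that passed edgeR's test, although 441 genes had an unadjusted p below 0.05. Its 23.2-fold rise carried the list of 7 NAD synthesis genes, where it was the only member to pass (adjusted p = 3.2e-11, adjusted p = 0.0013 with an estimated correlation). The 2 other lists that passed camera held no gene that passed. Proteasome subunits had a median log2 fold change of 0.17 over 31 genes (adjusted p = 8.75e-05, adjusted p = 0.81 with an estimated correlation). Macrophage and monocyte markers had a median of -0.69 over 12 genes (adjusted p = 0.0158, adjusted p = 0.81 with an estimated correlation), and without WT_4m replicate 3 the direction turned, with a median of -0.07 and an adjusted p of 0.873. The other 35 lists did not pass (adjusted p from 0.0672 to 0.925). Over 620 listed genes, 2 rose when adjusted over the list alone. Examples of abundant genes near their WT level are mt-Co1 (-0.12, SE 0.16), the fast myosin Myh4 (-0.13, SE 0.14) and Gapdh (-0.01, SE 0.14). DESeq2 called 2 genes and limma-voom 1, and edgeR called 2 without OE_4m replicate 3. The number of lists that passed was 8, 8 and 6 without WT_4m replicates 1, 2 and 4, and 9, 6 and 8 without OE_4m replicates 1, 2 and 3. Groups did not overlap for 5.29% of genes, against 5.71% by chance. The authors' deposited table listed 4 genes below an adjusted p of 0.05: Nampt, Nuak1, Dysf and Ampd1.

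At 24 months, overexpression of Nampt tests what added Nampt does in old muscle. Nampt was again the only gene of 9144 that passed, and 671 genes had an unadjusted p below 0.05. Slow fibre genes stood higher as a list, with a median log2 fold change of 2.07 over 11 members (adjusted p = 8.13e-11, adjusted p = 0.344 with an estimated correlation). None of them passed over all genes and 9 rose when adjusted over the list alone. The slow myosin Myh7 measured 110 ± 48.5 CPM in MCK-NamptOE and 26.3 ± 30.7 CPM in WT, with WT libraries from 0.362 to 63.3 CPM and MCK-NamptOE libraries from 44.4 to 150 CPM. Tnni1 measured 25.7 ± 17.7 CPM against 5.26 ± 4.69 CPM, and Csrp3, the most expressed member, had a log2 fold change of 2.07 (SE 0.89, adjusted p = 0.657). Myh7 and Tnni1 were picked after their values were seen.

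Respiratory chain genes moved with the slow fibre genes at 24 months. The lists for complex I (median 0.40 over 36 genes, adjusted p = 1e-16) and complexes II to V (median 0.43 over 42 genes, adjusted p = 2.92e-22) passed camera, both at adjusted p = 0.359 with an estimated correlation. None of their genes passed over all genes, while 23 genes of complexes II to V rose when adjusted over the list alone. Atp5b had a log2 fold change of 0.29 (SE 0.14). OE_24m replicate 4 was the highest library for both lists, and without it their medians were 0.19 and 0.24 (adjusted p = 1.09e-06 and 3.05e-11). That library also held the most Nampt, 9533 CPM against 4107 to 5736 CPM in the other OE_24m libraries. Its share of reads on no gene was 5.467%, against 6.46 to 6.653% in those libraries. Whether either bears on these lists was not tested. Fatty acid oxidation (median 0.28, adjusted p = 6.46e-07), the tricarboxylic acid cycle (0.22, 2.07e-06), mitochondrially encoded mRNAs (0.23, 0.00851) and regulators of mitochondrial biogenesis (0.19, 0.0244) also passed, with adjusted p = 0.376, 0.376, 0.451 and 0.359 with an estimated correlation. Without OE_24m replicate 4 the medians of fatty acid oxidation and biogenesis were 0.18 and 0.12, and without WT_24m replicate 4 those of the mitochondrially encoded and biogenesis lists were 0.15 and 0.11, with adjusted p of 0.15 and 0.0999. Without OE_24m replicate 3 the biogenesis list had an adjusted p of 0.108.

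The antigen presentation list was lower (median -0.42 over 11 genes, adjusted p = 4.59e-05, adjusted p = 0.282 with an estimated correlation), with 4 genes falling when adjusted over the list alone, and B2m at -0.25 (SE 0.16). Smooth muscle markers (median 0.28, adjusted p = 0.0224), calcium handling genes (-0.13, 0.0453), antioxidant genes (0.13, 0.0279), proteasome subunits (0.14, 0.00216) and extracellular matrix genes (-0.07, 0.0317) passed with smaller medians, and had adjusted p = 0.379, 0.454, 0.376, 0.653 and 0.722 with an estimated correlation. Without OE_24m replicate 4 the medians of the antioxidant, proteasome, matrix and smooth muscle lists were 0.07, 0.02, 0.05 and 0.10 (adjusted p of 0.24, 0.761, 0.59 and 0.108), and without WT_24m replicate 2 the smooth muscle median was 0.13 (0.179) and the calcium handling list had 0.238. The calcium handling median was -0.07, -0.08 and -0.08 without WT_24m replicate 4, OE_24m replicate 1 and OE_24m replicate 3 (adjusted p of 0.14, 0.0798 and 0.157), and antigen presentation stood at -0.27 without WT_24m replicate 1. The matrix median was -0.17 and -0.04 without WT_24m replicates 2 and 3, and -0.02, -0.19 and -0.27 without OE_24m replicates 1, 2 and 3. The list of 7 NAD synthesis genes passed with Nampt as its only member to pass (adjusted p = 3.55e-11, adjusted p = 0.00192 with an estimated correlation). The other 24 lists did not pass (adjusted p from 0.054 to 0.982), and over the 620 listed genes 35 rose and 8 fell when adjusted over the list alone. Single genes outside Nampt did not pass in edgeR, DESeq2 called 4 genes and limma-voom 1, and edgeR called 2 without WT_24m replicate 3 or without OE_24m replicate 1. Groups did not overlap for 4.69% of genes, against 2.86% by chance. The authors' deposited table listed 19 genes below an adjusted p of 0.05, among them Nampt, Idh2 (log2 fold change 1.06), Egln3 (1.88), Olfm1 (1.13) and Srebf1 (-0.56).

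The comparison of 24 with 4 months in WT mice shows what ageing does without a transgene. Old WT muscle held less transcript of type I collagen and of the vascular genes Rgs5 and Cdh5, and more transcript of the immunoglobulin light chain Igkc. Matrix, endothelial and smooth muscle genes stood lower as lists by camera, with adjusted p = 0.0562, 0.0777 and 0.0562 with an estimated correlation. Col1a1 fell from 22.2 ± 8.44 to 6.58 ± 2.58 CPM (log2 fold change -1.77, SE 0.26, adjusted p = 0.00618), and Col1a2 fell from 29.3 ± 12.5 to 10.8 ± 2.28 CPM (-1.45, SE 0.24, adjusted p = 0.011). The pericyte gene Rgs5 (-0.82, SE 0.14, adjusted p = 0.0113) and the endothelial cadherin Cdh5 (-0.71, SE 0.14, adjusted p = 0.0268) fell as well. Igkc rose from 1.09 ± 0.929 to 10.4 ± 4.9 CPM (3.05, SE 0.56, adjusted p = 0.0302), and without WT_4m replicate 2 its value was 3.71 (adjusted p = 0.0538). Of the 14 genes called, Col1a1 alone passed in each of the 15 edgeR fits that left out 1 library.

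In all, 14 of 9144 genes changed, 6 higher and 8 lower, with 781 genes at an unadjusted p below 0.05. The other rises were the muscle-secreted peptide Ostn (2.25, SE 0.37), Tmem132b (1.43, SE 0.25), Amy1 (1.10, SE 0.18), the endoplasmic reticulum chaperone Hspa5 (0.79, SE 0.16) and Amot (0.68, SE 0.14). The other falls were Nrep (-1.49, SE 0.28), the guanylate-binding protein Gbp7 (-1.20, SE 0.25), Mlf1 (-0.93, SE 0.17) and Lonrf1 (-0.87, SE 0.18). Amylase genes are near-copies of each other, so the count of Amy1 is uncertain. In edgeR the number of calls was 8, 4, 7 and 8 without WT_4m replicates 1, 2, 3 and 4, it was 9, 2, 8 and 9 without WT_24m replicates 1, 2, 3 and 4, and 22 without OE_4m replicate 3. It was 0 when all 23 libraries shared a fit, with 911 genes at an unadjusted p below 0.05, while DESeq2 called 42 genes and limma-voom 39. Groups did not overlap for 5.4% of genes, against 2.86% by chance. The authors' deposited table held 248 genes below an adjusted p of 0.05, and all 14 genes called here were among them in the same direction.

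Extracellular matrix genes were the list with the smallest p-value (28 genes, median -0.81, adjusted p = 3.87e-29, adjusted p = 0.0562 with an estimated correlation). The 2 collagens named above fell over all genes, and 17 genes fell adjusted over the list alone. Endothelial markers (13 genes, median -0.47, adjusted p = 2.52e-08) and smooth muscle and pericyte markers (9 genes, median -0.48, adjusted p = 2.09e-08) each had 1 gene falling and 4 and 3 adjusted over the list alone, with adjusted p = 0.0777 and 0.0562 with an estimated correlation. B and plasma cell markers rose as a list of 3 measured genes (median 2.16, adjusted p = 6.05e-08, adjusted p = 0.00409 with an estimated correlation), with 1 rising and 3 adjusted over the list alone. Tendon markers (median -0.66, adjusted p = 0.0194) and macrophage markers (-0.71, 0.000682) were lower, at adjusted p = 0.328 and 0.453 with an estimated correlation, and without WT_4m replicate 3 their medians were -0.42 and -0.11 and their adjusted p 0.0981 and 0.657. Without WT_24m replicate 3 the tendon median was -1.02. WT_4m replicate 3 was also the highest library of its group for matrix genes. Without it, the red blood cell list (median -0.72, adjusted p = 0.0379, adjusted p = 0.328 with an estimated correlation) had a median of -0.31 and an adjusted p of 0.451, and the interferon list (-0.39, 0.0435, adjusted p = 0.158 with an estimated correlation) reached 0.266.

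Immediate early genes (median 0.39, adjusted p = 0.000113), denervation genes (0.30, 0.00271) and protein folding genes (0.13, 0.00697) were higher as lists, and fast fibre genes (-0.17, 0.000833), integrated stress response genes (-0.19, 0.0127), atrophy genes (-0.08, 0.0427) and mitochondrially encoded mRNAs (-0.20, 0.0435) were lower. With an estimated correlation their adjusted p-values were 0.158, 0.116, 0.461, 0.333, 0.0777, 0.543 and 0.582. Of these genes only Hspa5 passed over all genes. Adjusted over the list alone, 1 immediate early, 3 denervation and 3 protein folding genes rose, 1 fast fibre and 1 stress response gene fell, and 1 atrophy gene rose while 4 fell. Without WT_24m replicate 4 the medians of denervation genes and mitochondrially encoded mRNAs were 0.16 and -0.12 (adjusted p of 0.0511 and 0.437). Protein folding genes stood at 0.25, 0.03, 0.22 and 0.05 without WT_4m replicates 1 and 4 and WT_24m replicates 1 and 3, with an adjusted p of 0.168 without the last. Atrophy genes stood at -0.15, -0.21, -0.01 and -0.20 without WT_4m replicates 1, 3 and 4 and WT_24m replicate 3, with an adjusted p of 0.355 without WT_4m replicate 4. Without WT_4m replicates 2 and 4 the mitochondrially encoded list stood at -0.31 and -0.13, and without WT_4m replicate 3 immediate early genes stood at 0.25. Slow fibre genes had a median of 0.79 and did not pass (adjusted p = 0.0609). The other 22 lists did not pass either, with adjusted p from 0.0581 to 0.943.

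Ageing in MCK-NamptOE mice, again 24 against 4 months, shows the same comparison with added Nampt. Collagens fell here too, and slow fibre genes stood higher as a list by camera, with adjusted p = 0.127 with an estimated correlation. Col1a2 fell from 36.6 ± 5.75 to 7 ± 1.56 CPM (-2.37, SE 0.27, adjusted p = 5.91e-05) and Col1a1 from 25.6 ± 2.6 to 7.11 ± 1.97 CPM (-1.85, SE 0.28, adjusted p = 0.00118). The collagen VI chains Col6a1 (-1.48, SE 0.27), Col6a2 (-1.58, SE 0.31) and Col6a3 (-1.55, SE 0.34) and Col15a1 (-1.70, SE 0.39) fell with them. The slow calcium pump Atp2a2 rose from 23.4 ± 3.69 to 101 ± 36.5 CPM (2.12, SE 0.43, adjusted p = 0.0435), and reached an adjusted p of 0.231 without OE_4m replicate 2.

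In all, 67 of 9144 genes changed, 29 higher and 38 lower, with 1010 at an unadjusted p below 0.05 and groups that did not overlap for 10.32% of genes, against 5.71% by chance. Other large rises were the amino acid transporter Slc6a17 (2.88, SE 0.56), sarcolipin, Sln (2.84, SE 0.61), which regulates the calcium pump, Ttc9 (2.66, SE 0.38), Tmem132b (2.09, SE 0.34), Tiam2 (1.86, SE 0.38), Amy1 (1.73, SE 0.20), Adprhl1 (1.67, SE 0.33), Slc1a1 (1.6, SE 0.33) and Slc25a33 (1.47, SE 0.35). Other large falls were Nrep (-2.20, SE 0.30), Enpep (-2.19, SE 0.48), AW112010 (-1.86, SE 0.37), Gbp7 (-1.81, SE 0.26) and the spermine oxidase Smox (-1.62, SE 0.28). Without OE_4m replicate 1 the count was 22 and without OE_4m replicate 2 it was 11. The 8 genes that passed in each of the 15 edgeR fits that left out 1 library were Col1a1, Col1a2, Casq1, Smox, Gbp7, Ttc9, Nrep and Amy1. The count was 2 with each library's mean of slow fibre genes as a covariate, while DESeq2 called 137 genes and limma-voom 167. That mean itself differs between the groups compared, so the covariate takes up part of the age contrast. The lost calls therefore cannot tell what the changes rest on. The authors' deposited table held 426 genes below an adjusted p of 0.05, and 64 of the 67 genes were among them in the same direction.

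The slow fibre list had a median of 4.26 in this comparison (11 genes, adjusted p = 8.37e-14, adjusted p = 0.127 with an estimated correlation), with 1 gene rising and 10 adjusted over the list alone. Some members had few reads in OE_4m, such as Myh7 (1.31 ± 0.913 CPM) and Tnni1 (0.505 ± 0.874 CPM), though Atp2a2 had 23.4 ± 3.69 CPM. The size of this median is therefore uncertain. In the young mice slow fibre genes had a median of -0.89 with overexpression, which did not pass (adjusted p = 0.123). How much of the slow fibre rise comes from the young mice is therefore uncertain. Fast fibre genes were lower (18 genes, median -0.25, adjusted p = 2.35e-07, adjusted p = 0.139 with an estimated correlation). Casq1 (-1.07, SE 0.17), Myl1 (-0.68, SE 0.13) and Ampd1 (-0.60, SE 0.13) fell, and 6 fell adjusted over the list alone. Extracellular matrix genes were lower (28 genes, median -0.85, adjusted p = 1.82e-28, adjusted p = 0.0498 with an estimated correlation), 7 falling and 16 adjusted over the list alone. Endothelial markers were lower as well (median -0.38, adjusted p = 3.27e-05, adjusted p = 0.197 with an estimated correlation), with Cdh5 (-0.85, SE 0.15) and Pecam1 (-0.75, SE 0.16) falling and 4 adjusted over the list alone. Tendon markers (-1.25, adjusted p = 0.00448, 1 falling adjusted over the list alone) and antigen presentation genes (-0.48, adjusted p = 2.95e-05, 3 falling adjusted over the list alone) had adjusted p = 0.223 and 0.127 with an estimated correlation, and the tendon median was -0.81 without OE_4m replicate 3. B and plasma cell markers were higher (median 1.41, adjusted p = 0.000393, adjusted p = 0.0498 with an estimated correlation), with 3 rising adjusted over the list alone and none over all genes, and a median of 2.72 without OE_4m replicate 2.

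Fatty acid oxidation (median 0.39, adjusted p = 2.35e-07), complexes II to V (0.32, 9.46e-08), complex I (0.22, 0.00016), biogenesis regulators (0.20, 0.000406, 2 rising adjusted over the list alone) and the tricarboxylic acid cycle (0.19, 0.00636, 1 rising adjusted over the list alone) were higher as lists. With an estimated correlation their adjusted p-values were 0.294, 0.482, 0.556, 0.115 and 0.519. Without OE_24m replicate 4 the medians of complex I, complexes II to V and the tricarboxylic acid cycle were 0.04, 0.12 and 0.10 (adjusted p of 0.485, 0.0272 and 0.0641), and without OE_4m replicate 3 they were 0.41, 0.48 and 0.29. Without OE_4m replicate 2 complex I stood at 0.11 (adjusted p of 0.0532), and the tricarboxylic acid cycle had an adjusted p of 0.0879. Myogenic regeneration (0.52, adjusted p = 0.00862), denervation (0.18, 0.0206, with Sln rising), protein folding (0.15, 0.00448) and immediate early genes (0.35, 0.0425) were higher, and glycolysis genes lower (-0.20, 0.000393, with Pgm2 falling). With an estimated correlation these had adjusted p = 0.253, 0.238, 0.454, 0.462 and 0.294. Adjusted over the list alone, 2 regeneration genes rose and 1 fell, 2 denervation genes rose, and 1 glycolysis gene rose and 1 fell. Their adjusted p rose to 0.0918 without OE_24m replicate 1, 0.0811 without OE_24m replicate 3, 0.0641 without OE_24m replicate 4, 0.569 without OE_4m replicate 1 and 0.168 without OE_4m replicate 3, in that order. Without OE_4m replicate 3 the glycolysis and folding medians were -0.13 and 0.24, and the denervation median was 0.10, 0.10 and 0.12 without WT_24m replicate 1, WT_24m replicate 3 and OE_24m replicate 3. The other 21 lists did not pass (adjusted p from 0.0901 to 0.948). In 2 of them single genes changed, with Flnc (1.15, SE 0.24) higher and Ano5 (-0.60, SE 0.14) lower in the dystrophin complex list (1 and 2 adjusted over the list alone) and Sypl2 (-0.67, SE 0.15) lower in the calcium handling list.

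**Figure D3:**
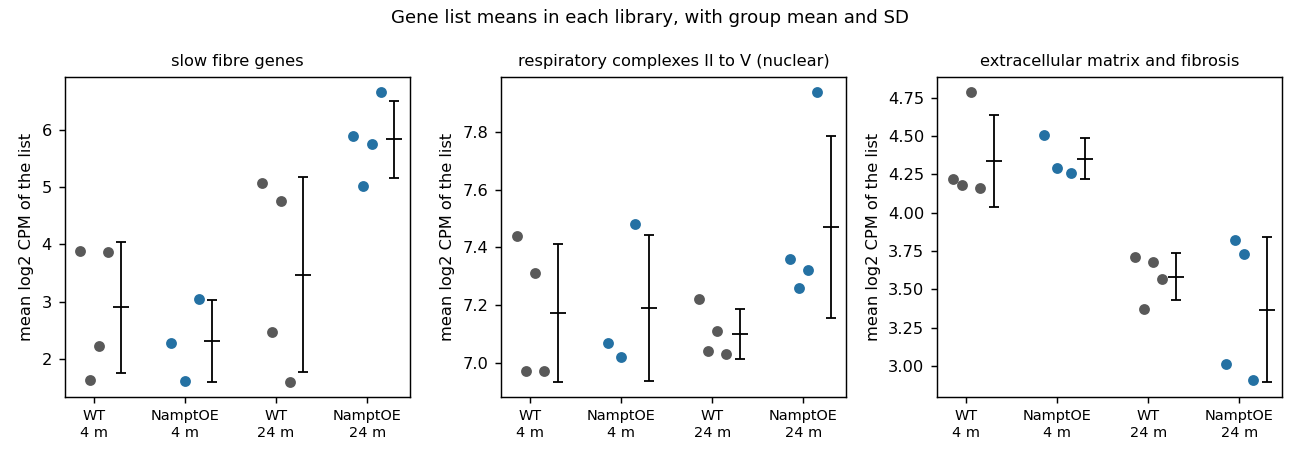
Mean log2 CPM of 3 gene lists in each library at 4 and 24 months (m, months; points are libraries, bars the group mean and SD). OE_24m replicate 4 is the highest library for respiratory complexes II to V, at 7.94 against 7.26 to 7.36 in the other MCK-NamptOE libraries of that age, and the matrix list is lower at 24 months in both genotypes.

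Whether ageing differed between the genotypes was tested as an interaction. No gene passed edgeR's test (smallest adjusted p = 0.442), with 498 of 9144 genes at an unadjusted p below 0.05, and DESeq2 called 1 and limma-voom 0. By camera 10 lists differed (adjusted p from 1.1e-10 to 0.0484), and none of them did with an estimated correlation (adjusted p from 0.492 to 0.539) or by fry. The age effect was higher with overexpression for slow fibre genes (difference of log2 fold changes, list median 2.90), fatty acid oxidation (0.46), complexes II to V (0.40), smooth muscle markers (0.40), complex I (0.36), mitochondrially encoded mRNAs (0.35), the tricarboxylic acid cycle (0.27) and biogenesis regulators (0.22), and lower for antigen presentation (-0.48) and calcium handling (-0.16). The slow fibre difference joins a rise at 24 months (2.07) with a lower median at 4 months (-0.89, adjusted p = 0.123), the latter not passing. Its size is uncertain, since some slow fibre genes had few reads in OE_4m. Without OE_24m replicate 4 the differences for complex I, complexes II to V and smooth muscle were 0.14, 0.22 and 0.23, the last with an adjusted p of 0.0815. Without WT_4m replicate 1 fatty acid oxidation and smooth muscle stood at 0.27 and 0.22, and biogenesis and smooth muscle had adjusted p of 0.16 and 0.138. Smooth muscle stood at 0.25 (adjusted p = 0.113) without WT_24m replicate 2, calcium handling at -0.10 (0.0815) without WT_4m replicate 4, and complex I at 0.55 without OE_4m replicate 3. Without WT_24m replicate 2 the calcium handling list had an adjusted p of 0.0828. The other 28 lists did not pass.

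Genes that changed with age in either genotype tended to share direction. Among the rises, 2 genes were called in both, Amy1 and Tmem132b, against 0.019 expected of independent lists. Among the falls, 5 were called in both, Cdh5, Col1a1, Col1a2, Gbp7 and Nrep, against 0.0332 expected. The shared rises were 0 without WT_4m replicate 2 and 1 without OE_4m replicate 2 or WT_24m replicate 2. The shared falls were 2 without WT_4m replicate 2 or 3, 1 without WT_24m replicate 2, 8 without OE_24m replicate 4, and 3 without WT_4m replicate 4, OE_4m replicate 2, WT_24m replicate 1, 3 or 4, or OE_24m replicate 1. All 14 genes called in WT had the same direction with overexpression, with a slope of 0.98 through the origin, and 59 of the 67 genes called with overexpression had the same direction in WT, with a slope of 0.42. Genes chosen in a genotype shrink when read in another, and 3 of the 14 and 45 of the 67 had an interaction at an unadjusted p below 0.05. Across all 9144 genes, which are not independent replicates, the log2 fold changes correlated at r = 0.333 (rho = 0.211).

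**Figure D4:**
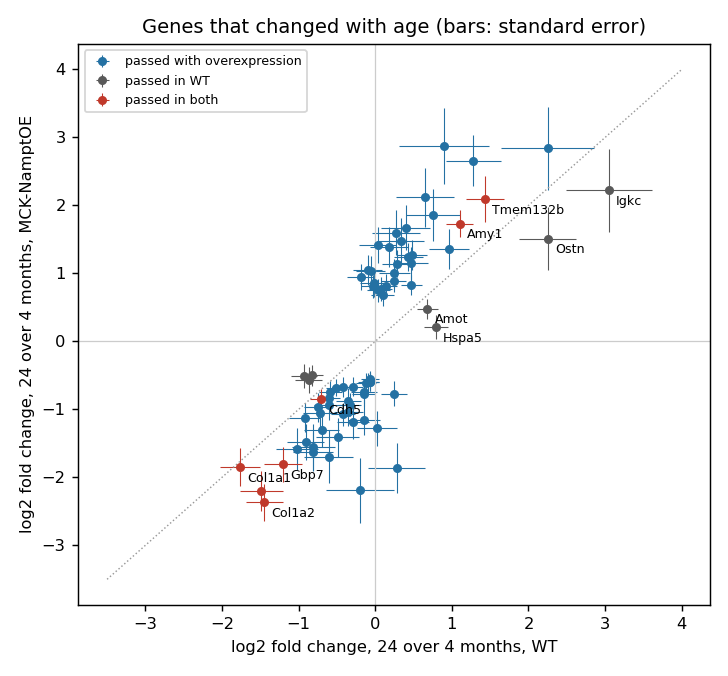
Log2 fold change from 4 to 24 months in WT (horizontal axis) and in MCK-NamptOE (vertical axis) for the genes that passed in either, with standard errors as bars and a dotted line of equal change. Col1a1 and Col1a2 are low in both, at -1.77 and -1.45 in WT and -1.85 and -2.37 with overexpression.

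The mNKO change at 7 months was also set against ageing and overexpression, comparisons that share no library. Collagen I moved in opposite directions, Col1a1 (3.32, SE 0.35) and Col1a2 (2.98, SE 0.28) rising in mNKO and falling with age. Across 9130 genes the mNKO change correlated with the ageing change in WT at r = -0.101 (rho = -0.057), with overexpression at 24 months at r = 0.122 (rho = 0.078), with overexpression at 4 months at r = -0.179 (rho = -0.125) and with ageing under overexpression at r = 0.143 (rho = 0.097). Without WT_4m replicate 3 or WT_24m replicate 2 the first was -0.017 or -0.061, and without OE_24m replicate 3 or WT_24m replicate 2 the second was 0.05 or 0.074. Genes are not independent, so neither these nor the shared calls below carry a p-value. Of the genes that rose with age in WT, 2 also rose and 3 fell in mNKO, against 1.15 and 1.93 expected, and of the genes that fell with age 4 also fell and 2 rose, against 2.58 and 1.53, too few to read. Read as lists in the other 5 comparisons, the 1743 genes higher and the 2943 genes lower in mNKO did not pass camera in any (smallest adjusted p = 0.053). With overexpression, 16 genes that rose with age also rose in mNKO against 5.35 expected, among them Atp2a2, Sln, Ttc9, Tiam2, Adprhl1 and Flnc, whose mNKO rise (0.36) reached an adjusted p of 0.136 without WT_7m replicate 3. A further 13 that fell with age, Col1a1, Col1a2, Col6a1, Col6a2, Col6a3 and Col15a1 included, rose in mNKO against 7.25 expected. Another 16 that fell with age also fell in mNKO against 12.2 expected, and 5 that rose with age fell in mNKO against 9.03 expected. These overlaps rest on single libraries. In the order given they were 2, 3, 7 and 3 without OE_4m replicate 1 (1.76, 2.55, 4.12 and 2.85 expected). Without OE_4m replicate 2 they were 1, 3, 4 and 1 (0.391, 1.76, 2.85 and 0.634 expected). With the slow fibre covariate, which left 2 genes called with age, they were 0, 0, 0 and 1, too few to read. The second was 7 and 8 without OE_24m replicates 1 and 4, the third 10 and 7 without OE_24m replicates 1 and 3, and the fourth 2 without WT_7m replicate 2 or mNKO_7m replicate 1 and 9 without OE_24m replicate 4.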

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

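The tests of a lower share of non-muscle cells with age and of a common dilution in mNKO, the total-count and slow fibre settings and the setting without 2 overexpression libraries were chosen after the results were seen.

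Slow fibre and respiratory chain genes stood higher with overexpression at 24 months, with a list median of 2.07 for slow fibre genes, and 0.40 and 0.43 for complex I and complexes II to V (0.19 and 0.24 without OE_24m replicate 4). These lists passed camera with the preset correlation but not with an estimated correlation. OE_24m replicate 4 also held the most Nampt (9533 CPM). Of the 15 libraries at 4 and 24 months it had the smallest share of reads on no gene (5.467%). Neither was tested as a source. For the respiratory chain genes alone the median difference between the groups was 0.39, and of the 35 splits of the 8 libraries only 1, the real one, gave as much (highest other 0.34). These genes had already stood out in the same 8 libraries, and 35 splits can show nothing rarer than 1 in 35. As many lists passed camera in 7 of 35 splits, so chance cannot be excluded here. Genes matched on length, GC content and expression had a median of 0.15 (0.11 to 0.19) against 0.42 for 78 respiratory chain genes, which argues against length or GC content as the whole source. More slow-fibre RNA in some samples and overexpression itself cannot be told apart, because the slow fibre mean also differs between the groups (by 2.36) and, as a covariate, took the respiratory chain difference from 0.36 (SE 0.17) to 0.14 (SE 0.21), a drop of 0.22 (SE 0.14), under 2 of its standard errors. Within groups the slow fibre and respiratory chain means correlated at r = 0.45 (permutation p = 0.0429; rho = 0.38, permutation p = 0.109; r = 0.48 without the 2 farthest libraries).

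Collagen and vascular genes stood lower at 24 than at 4 months in WT. Genes matched on length, GC content and expression had a median of 0.03 (-0.08 to 0.13) against -0.81 for matrix genes, which argues against length or GC content as the whole source. A lower share of all non-muscle cells would lower matrix and endothelial genes alike, and their per-library difference moved by -0.33 with age in WT (exact permutation p = 0.0857) and by -0.59 with overexpression. With 4 libraries a group this leaves a lower share and a change within those cells such that they cannot be told apart. Age itself stays open.

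In mNKO 53.07% of the tested genes changed, 6974 in all, and no other of the 35 splits of the 8 libraries called any in edgeR (highest other 0). This argues against chance for the gene count, although 35 splits can show nothing rarer than 1 in 35. With mitochondrial genes and the 20 most abundant genes out of the scaling, 99.4% of the calls kept their direction, which argues against a few abundant genes setting the result. A dilution of all muscle genes by 1 common factor was set against 181 genes of the muscle lists. Their log2 fold changes had an SD of 0.68 against a median SE of 0.18, a ratio of 3.87, so these genes did not share 1 factor. Respiratory chain and tricarboxylic acid cycle genes among them are not limited to muscle, so dilution need not lower all of them alike. The ratio therefore cannot decide on dilution. Dilution of muscle RNA, a higher share of other cells for the genes of those cells, and the loss of Nampt itself stay open.

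For other counts, the splits of the libraries gave these results. For the gene counts of ageing the real split called the most, with 14 genes in WT (1 of 35 splits as large, the real split itself, highest other 1) and 67 with overexpression (1 of 35, highest other 6). That argues against chance, but 35 splits can show nothing rarer than 1 in 35, and several counts were tested in this way. With overexpression the count is Nampt alone, and 3 of 35 splits called at least 1 gene at 4 months (highest other 19) and 3 of 35 at 24 months (highest other 4), which says nothing of Nampt itself, at 4107 CPM or more in every overexpression library and at most 253.2 CPM in every WT library of those ages. For the interaction the splits decide nothing, since any of the 100 of 100 drawn splits reaches the real count of 0 in edgeR (498 genes at an unadjusted p below 0.05, DESeq2 1 and limma-voom 0). The highest other there called 55, and this split and the split with 19 calls point to a structure of the samples, whose source was not tested. Chance cannot be excluded for the number of lists that passed camera, which was 20 in mNKO (7 of 35 splits as many, highest other 25), 3 and 14 with overexpression at 4 and 24 months (30 and 7 of 35, highest other 14 and 17), 15 and 17 with age in WT and with overexpression (5 and 2 of 35, highest other 21 and 19), and 10 for the interaction (28 of 100, highest other 18). For correlations across genes, 16 of 35 splits were as large as r = -0.101 for mNKO against ageing in WT (highest other 0.262), 11 of 35 as large as 0.122 for mNKO against overexpression at 24 months (-0.256), and 2 of 35 as large as 0.333 for ageing in both genotypes (-0.344), so chance cannot be excluded for any of these.

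A difference in ageing between genotypes was tested as an interaction by camera and passed for 10 lists, with median differences of 2.90 for slow fibre genes, 0.46 for fatty acid oxidation, 0.40 for complexes II to V, 0.40 for smooth muscle markers, 0.36 for complex I, 0.35 for mitochondrially encoded mRNAs, 0.27 for the tricarboxylic acid cycle, 0.22 for biogenesis regulators, -0.16 for calcium handling and -0.48 for antigen presentation. The slow fibre median was -0.89 at 4 months and 2.07 at 24 months, and some of its genes had few reads in OE_4m. Without OE_24m replicate 4 complex I, complexes II to V and smooth muscle stood at 0.14, 0.22 and 0.23, without WT_4m replicate 1 fatty acid oxidation and smooth muscle at 0.27 and 0.22, without WT_24m replicate 2 smooth muscle at 0.25, without WT_4m replicate 4 calcium handling at -0.10, and without OE_4m replicate 3 complex I at 0.55. None of the 10 passed with an estimated correlation (adjusted p from 0.492 to 0.539) or by fry. Biogenesis and smooth muscle had adjusted p of 0.16 and 0.138 without WT_4m replicate 1, and calcium handling 0.0828 without WT_24m replicate 2.

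Reads that HTSeq could not assign to a single gene stayed out of the gene counts, and of the reads on genes, on no gene and on several genes together they made up 0.432 ± 0.0257% in mNKO (n = 4) and 0.332 ± 0.021% in WT at 7 months (n = 4), a difference of 0.0995 percentage points (exact permutation p = 0.0286, adjusted p = 0.214 over 30 comparisons). Reads without a unique alignment (19.6 ± 2.48% against 26.6 ± 2.98%) and the share of the 10 most abundant genes (22.4 ± 1.06% against 32.3 ± 1.68%) were lower in mNKO, with the same exact and adjusted p. With 4 libraries a group no exact p below 0.0286 is possible, so these adjusted p-values cannot decide.

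Single libraries stood far from the other 3 of their group in 35 of 494 groups of values, where chance gives about 1 in 20, or 24.7. The number after each library is its gap to the nearest library over the range of the group. In mNKO_7m, replicate 3 was highest for Ighg3 (0.875) and lowest for Bst1 (0.848) and the chemokine list (0.956). Replicate 2 was lowest for Thbs4 (0.878), and replicate 4 was lowest for Clcn1 (0.948) and the sex-linked list (0.907) and highest for Anxa2 (0.93) and Cpt1a (0.957).

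In WT_7m, replicate 4 was highest for Tmem8c (0.952), Mmp12 (0.988), F10 (1), Col1a2 (0.831) and Ttc9 (0.855) and lowest for the glycolysis list (0.882). Replicate 3 was lowest for Cd14 (0.903), Tnnc1 (0.874), Aurkb (0.952), Csf3r (0.901), Flnc (0.841) and the neutrophil list (0.885). Replicate 2 was highest for Cd72 (0.98) and Sprr1a (1) and lowest for Nampt (0.831), and replicate 1 was highest for Msln (1) and Ddx3y (0.83). Some of these gaps are steps of a few reads. Msln, F10 and Sprr1a had 1, 2 and 1 reads over the WT_7m libraries, and Aurkb had 0 CPM against 0.0572 to 0.06 CPM. Such flags are among the 35 and do not show a library that stands far apart.

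In OE_24m, replicate 4 was highest for complex I (0.861) and complexes II to V (0.853). Replicate 3 was highest for Slc6a17 (0.832) and lowest for the share of mitochondrial counts (0.867), and replicate 2 was lowest for NAD-consuming enzymes (0.846). In WT_24m, replicate 3 was highest for the p53 list (0.833). In WT_4m, replicate 3 was highest for matrix genes (0.905) and lowest for the p53 list (0.929), replicate 2 was highest for Amot (0.889), and replicate 1 was highest for B and plasma cell markers (0.844).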

How the results depend on the processing

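The tests with total counts, with fewer abundant genes in the scaling, without 2 overexpression libraries and with a slow fibre covariate were chosen after the result was seen. The mNKO count of 6974 genes ran from 6090 to 7706 over all settings (6173 to 6843 with a library left out), with no call in the opposite direction, but with total counts, the setting with 7706 calls, 67.2% of the 6974 calls (4686) were shared. Nampt kept its direction and its call, from -2.81 to -2.53 in mNKO, 4.44 to 4.62 with overexpression at 4 months and 4.63 to 5.07 at 24 months with a library left out.

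The other gene counts moved, and the cause was not tested. For overexpression at 4 months (1 gene) they were 60 with no filter, 2 with DESeq2, 2 without the 2 overexpression libraries, and 1 to 2 with a library left out. At 24 months (1 gene) they were 130 with no filter, 4 with DESeq2, and 1 to 2. For ageing in WT (14 genes) they were 187 with no filter, 42 with DESeq2 (13 of the 14 shared), 39 with limma-voom (12 shared), 0 with edgeR on all 23 libraries (911 genes at an unadjusted p below 0.05), and 2 to 22. For ageing with overexpression (67 genes) they were 354 with no filter, 137 with DESeq2 (67 shared), 167 with limma-voom (66 shared), 2 with the slow fibre covariate, and 11 to 87. The covariate itself differs between those groups, so that count cannot tell what the calls rest on. For the interaction (0 genes in edgeR, 498 at an unadjusted p below 0.05) they were 106 with no filter, 1 with DESeq2, 0 with limma-voom, and 0 to 0.

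Lists that passed went from 20, 3, 14, 15, 17 and 10 (mNKO, overexpression at 4 and 24 months, ageing in WT and with overexpression, interaction) to 0, 1, 1, 1, 2 and 0 with an estimated correlation and to 27, 1, 1, 5, 7 and 0 with fry. With a library left out they ran 20 to 23, 3 to 9, 10 to 17, 10 to 19, 15 to 19 and 8 to 15. Of 79 list results, 5 passed with an estimated correlation, 33 with fry and 79 with DESeq2 size factors. No direction was reversed with fry or DESeq2 size factors. With an estimated correlation the direction was carried over and not checked. Without WT_4m replicate 3 the macrophage list at 4 months turned (adjusted p = 0.873), and with total counts the medians of 6 of the 20 mNKO lists turned positive. Correlations across genes ran from -0.14 to -0.017 (mNKO and ageing), 0.05 to 0.168 (mNKO and overexpression at 24 months) and 0.24 to 0.377 (both ageing changes) with a library left out, and were -0.058, 0.181 and 0.362 at 10 CPM or more.

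Small changes were often missed in simulated data with these depths and group sizes and 200 changed genes per comparison. Of simulated 2-fold changes, 64.2% were recovered with the 7-month libraries, 55.2 to 68.7% in the 4 other pairwise comparisons and 23.9% in the interaction. Of 1.5-fold changes, 17.9%, 14.9 to 25.4% and 1.5% were recovered, in that order. An adjusted p depends on how many genes change. The 7-month values therefore do not show what was missed in mNKO, where 6974 genes changed. No paired analysis was possible because the titles name separate animals and carry no shared replicate number.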

Other observations

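The reading of single ageing genes in mNKO below was chosen after the ageing result was seen, and it rests on no further test.

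Of the 14 genes that changed with age in WT, 11 also changed in mNKO muscle at 7 months, 6 in the same direction and 5 in the opposite direction. Independent lists would give 1.15 genes rising in both and 2.58 falling in both. They would give 1.53 rising in mNKO and falling with age, and 1.93 the reverse, so these counts are too few to read. The immunoglobulin light chain Igkc (3.61 in mNKO, 3.05 with age) and the chaperone Hspa5 (1.54 and 0.79) rose in both, and Lonrf1 (-1.30 and -0.87), Mlf1 (-0.96 and -0.93), Gbp7 (-1.01 and -1.20) and Nrep (-1.0 and -1.49) fell in both. Col1a1 (3.32 and -1.77) and Col1a2 (2.98 and -1.45) rose in mNKO and fell with age. Ostn (-4.33 and 2.25), Tmem132b (-3.95 and 1.43) and Amy1 (-1.33 and 1.10) fell in mNKO and rose with age. Rgs5, Cdh5 and Amot did not pass in mNKO.

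Principal components of the 7-month libraries were computed on the 500 genes that varied most between them. On the first (88.1% of the variance of those genes), WT replicates lay at -38.7, -47, -47.3 and -23.5. Replicate 4, the closest to mNKO, was also the WT library highest for Mmp12 and Tmem8c.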
